A study of Mus musculus with 6 samples.

How the data were processed

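RNA-seq was analysed for 6 samples of mouse embryonic fibroblasts infected with Gata4, Hand2, Mef2c and Tbx5, 3 treated with DMSO and 3 with DAPT until day 15. Groups and replicate numbers were taken from the sample labels. The labels give the DAPT concentration as 2.5 mM, and that unit was not checked here. The deposited table holds whole numbers per gene symbol, taken here as raw counts because the processing notes name a counting tool. It has 1 column per sample, and 0 columns were left unused. The submitters' processing notes name TopHat2 2.0.0, featureCounts, DESeq 1.6.3 and the genome build mm10, with no role or order. The annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping antisense gene cannot be told apart. Genes with near-identical copies can lose or share reads: Gapdh, which has many pseudogenes, was counted at 6.88 to 12.4 CPM while Actb was counted at 3288 to 3942 CPM.

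The table has 43259 entries, none of which lacks a gene name, and 75 were written with a decimal point. Symbols were in capitals, and 39383 matched exactly 1 gene of GENCODE release M21 when case was ignored. Coordinates of named genes are those of that annotation on GRCm38, the assembly also called mm10, 1-based, and span the whole gene. No genome sequence was used. Total counts were 26946319, 30642276 and 27601265 in DMSO 1, 2 and 3 and 25979335, 24533607 and 26104233 in DAPT 1, 2 and 3. A gene with 0 counts can be present at up to 3 counts per library, which is 0.098 to 0.122 CPM and covers counting error only. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of 4.85 or more), so each was used as 1 sample.

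Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (15785 genes holding 99.91% of the counts), libraries were scaled by TMM, and DAPT was compared with DMSO by the quasi-likelihood F test (estimateDisp, glmQLFit with robust estimation, glmQLFTest; two-sided), with group as the only term and Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05. Standard errors were obtained as the absolute log2 fold change divided by the square root of the F statistic, and CPM values are TMM-scaled. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation between genes of 0.01 and adjustment over 29 lists with at least 3 measured members, which compares a list with all other genes. The same lists were tested with an estimated correlation and with fry, which asks whether a list's genes move one way on balance and makes no comparison with other genes. With an estimated correlation 0 of the 29 lists passed, against 12 higher and 4 lower with the preset value. With the preset value another division of the 6 libraries into 3 and 3 also called up to 13 lists. Every such division still holds more DMSO libraries on one side, so a true group difference could add to these calls. Because no list passed with an estimated correlation, the preset p-values are not taken to allow for the spread between libraries in full. Calls were also adjusted over each list alone.

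The lists, the design, the alternatives and the rule for naming genes were chosen from the labels and textbook knowledge before the data were examined. The 12 primary lists cover the delivered factors, Notch targets, sarcomere, calcium handling, ion channels, cardiac transcription factors, Mef2 targets, skeletal muscle, smooth muscle, fibroblast and extracellular matrix, cell cycle and oxidative metabolism. The other 17 cover Notch components, cardiac hormones and chamber genes, TGF-β response, glycolysis, 7 sets of markers of other cell types (endothelial, macrophage, neural, epithelial, adipocyte, cartilage and bone, mesothelial), interferon response, inflammatory genes, stress genes, ribosomal proteins, mitochondrially encoded genes and histones. Some genes stand in more than 1 list, such as Myh6 in the sarcomere and Mef2 lists and Casq2 in the calcium and smooth muscle lists. Always named were the 4 factors, Hes1, Hey1, Heyl, Nrarp, Myh6, Tnnt2, Actc1 and Nppa. Also named were the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM and no overlap between groups, leaving out predicted genes, and the called members of each list with the smallest adjusted p (up to 3 for a primary list, 1 for another list), or the member with the highest mean CPM where none was called. A gene that this rule names is not reported here. Other members, and genes named in the closing section, were chosen after their values were seen.

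The test was checked on simulated counts drawn for the same 15785 genes and library sizes with 200 genes changed. It recovered 55.2% of genes changed 1.5-fold, 64.2% of those changed 2-fold and 89.4% of those changed 3-fold, with 19 false among 158 calls, and made 2 calls when no gene was changed. All 5 lists raised in the simulation were called and 0 of 15 unchanged lists were. Genes were drawn independently of each other there, so this check does not cover lists whose members are correlated. In the real libraries that correlation was estimated at 0.67 for the sarcomere list. Alternatives were scaling by DESeq2 size factors or by total counts, no filter or a mean of at least 1 CPM, the DESeq2 1.42.0 Wald test, limma-voom, an added log2 fold change threshold, the replicate number as a block, and leaving out each library in turn. Principal components used log2 CPM with a prior count of 2 for the 500 most variable genes. A comparison of 1 value between 3 and 3 samples cannot reach a two-sided exact permutation p under 0.1, so none is given.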

Results

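RNA-seq was carried out on total RNA from cultured cells. The cells were mouse embryonic fibroblasts, taken at embryonic day 13.5 from C57/BL6 mice and infected with GHMT, a mixture of the cardiac transcription factors Gata4, Hand2, Mef2c and Tbx5 that turns part of a fibroblast culture toward a cardiomyocyte-like state. For 15 days the infected cells received either DAPT, an inhibitor of the γ-secretase that releases the intracellular part of Notch receptors, or its solvent DMSO as the vehicle control. Each group held 3 samples. The deposited gene counts summed to 26946319, 30642276 and 27601265 in DMSO samples 1, 2 and 3. In DAPT samples 1, 2 and 3 they summed to 25979335, 24533607 and 26104233. A gene with 0 counts in a library could have been present at up to 0.098 to 0.122 CPM (the count scaled to a common library total), a limit that covers counting error only. The labels do not say whether the replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

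The comparison asked how DAPT changed the transcriptome of cells undergoing GHMT-driven cardiac reprogramming. With DAPT, genes of the heart muscle contractile apparatus rose: the α-myosin heavy chain gene Myh6 was 2.10-fold higher, the Z-disc gene Actn2 2.03-fold and the cardiac actin gene Actc1 1.93-fold. Genes of calcium handling (Pln, Srl, Sln), of the smooth muscle contractile apparatus (Myh11, Mylk) and the atrial potassium channel gene Kcnj3 rose as well. Fibroblast and extracellular matrix genes were lower as a list (adjusted p = 0.35 with an estimated correlation), and Fap, a fibroblast activation marker, fell to 0.41 times its DMSO level. Cell cycle genes were lower as a list (adjusted p = 0.35 with an estimated correlation), although none of them passed the test across all genes. In all, 96 genes rose and 23 fell among 15785 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), with median log2 fold changes of 0.66 and -0.73.

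The 3 DAPT values lay all above or all below the 3 DMSO values for 3909 tested genes (24.8%), and these included the 119 called genes. The mean share expected by chance is 10%. Genes vary together and the share was not obtained for other splits of the libraries, so whether 24.8% exceeds chance was not tested. At an unadjusted p under 0.05, 1449 genes were higher and 1527 lower, and DESeq2 called 423 higher and 415 lower. The number of calls rested on single libraries. Without DMSO 3, edgeR called 827 genes higher and 1044 lower, and without DMSO 1 it called 101 and 32. It called 1 and 0 without DMSO 2, 1 and 0 without DAPT 1, 3 and 0 without DAPT 2, and 0 and 0 without DAPT 3 (1145 and 1173 at an unadjusted p under 0.05). Of the 25 named genes that passed in all 6 libraries, 25 passed without DMSO 3, 24 without DMSO 1, 2 without DAPT 2, 1 without DMSO 2, 1 without DAPT 1 and 0 without DAPT 3. Of the same genes, 25 of 25 kept their direction whichever library was left out. DMSO 3 lay closer to the DAPT libraries than the other DMSO libraries did, with a first principal component score of -6.37 against 24.6 and 15.9 in DMSO 1 and 2 and -7.68 to -15.1 in the DAPT libraries. This component held 53.6% of the variance of the 500 most variable genes.

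Transcripts of the delivered factors were abundant in every library, and viral and endogenous copies cannot be told apart in these counts. Gata4 (chromosome 14, 63198922 to 63271692) was counted at 1225 ± 165 CPM in DMSO and 1425 ± 146 in DAPT (mean ± SD, n = 3 each), a log2 fold change of 0.22 ± 0.11 (SE; edgeR adjusted p = 0.333). Hand2 stood at 625 ± 77.8 and 762 ± 67.9 CPM (adjusted p = 0.204). Mef2c stood at 945 ± 164 and 1095 ± 114 (adjusted p = 0.417), and Tbx5 at 1174 ± 196 and 1288 ± 132 (adjusted p = 0.606). None of the 4 passed by edgeR, either across all genes or adjusted over the list alone, and none by DESeq2. Hand2 alone had an unadjusted p under 0.05. As a list they were higher with DAPT by limma's camera test (median log2 fold change 0.22, adjusted p = 0.0454). The list had an adjusted p = 0.571 with an estimated correlation, and 0.164 without DMSO 1, 0.0871 without DMSO 2, 0.0718 without DAPT 1 and 0.144 without DAPT 2. Without DMSO 3, Hand2 passed with a log2 fold change of 0.39 (adjusted p = 0.0254). In mean log2 CPM of the list relative to all libraries the groups overlapped. DMSO 3 lay at 0.118, against 0.111, 0.25 and -0.033 in DAPT 1, 2 and 3.

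Of 14 Notch target genes, 9 had enough counts to be tested, and none passed across all genes by edgeR (1 higher and 3 lower at an unadjusted p under 0.05; DESeq2 called 2 lower). Heyl, a transcriptional repressor induced by Notch (chromosome 4, 123233556 to 123249875), was counted at 13.6, 10.0 and 16.2 CPM in DMSO 1, 2 and 3 and at 6.91, 7.51 and 8.14 CPM in DAPT 1, 2 and 3. Its log2 fold change was -0.82 ± 0.17 (edgeR adjusted p = 0.0872; DESeq2 adjusted p = 0.0013). It was the 1 member that fell adjusted over the list alone (adjusted p = 0.0123). It also passed across all genes without DMSO 3 (edgeR adjusted p = 0.0231). Hey1 had a log2 fold change of -0.99 ± 0.41 near the detection limit (1.32 ± 0.75 CPM in DMSO, 0.66 ± 0.14 in DAPT, edgeR adjusted p = 0.254), and -0.43 without DMSO 1. Hes1 was counted at 33.0 ± 2.32 and 32.2 ± 0.44 CPM (adjusted p = 0.803) and Jag1 at 80.4 ± 5.78 and 77.3 ± 5.26 CPM (adjusted p = 0.711). Nrarp was at or near 0, with 0, 1 and 0 counts in DMSO and 2, 1 and 1 in DAPT, and was not tested. The list was not shifted (camera adjusted p = 0.363, median log2 fold change -0.12). Nor were the 29 measured Notch pathway components (camera adjusted p = 0.792, 0 passing by edgeR with 2 higher and 4 lower at an unadjusted p under 0.05, 2 higher and 0 lower by DESeq2). Kat2b rose adjusted over the list alone (0.34 ± 0.07, edgeR adjusted p = 0.0292). Without DMSO 3, 2 components rose and 3 fell.

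Cardiac sarcomere genes moved together. All 35 measured members had a positive log2 fold change (median 0.41), 6 rose across all genes, 29 did not pass, and 28 rose adjusted over the list alone. Myh6 (chromosome 14, 54941921 to 54966927) increased from 1062 ± 106 to 2226 ± 231 CPM, a log2 fold change of 1.07 ± 0.10 (edgeR adjusted p = 0.0152). Actn2 (chromosome 13, 12269426 to 12340760) increased from 72.9 ± 5.45 to 148 ± 16.9 CPM (1.02 ± 0.09, adjusted p = 0.0133). The atrial myosin light chain gene Myl7 increased from 407 ± 58.2 to 750 ± 32.1 CPM (0.88 ± 0.10, adjusted p = 0.0204) and Actc1 from 818 ± 126 to 1578 ± 91.7 (0.95 ± 0.11, adjusted p = 0.0212). The cardiac troponin T gene Tnnt2, the most abundant of the always-named cardiac genes, stood at 6630 ± 936 and 9534 ± 664 CPM, with groups that did not overlap. It did not pass across all genes (0.52 ± 0.12, adjusted p = 0.0932; 0.00344 without DMSO 3). Camera placed the list above all other genes (adjusted p = 2.93e-21). The list had an adjusted p = 0.333 with an estimated correlation, the correlation between members being estimated at 0.67. The number of members passing was 25 without DMSO 3, 0 without DMSO 2, DAPT 1 or DAPT 3, and 1 without DAPT 2. Reads from Myh6 and Myh7, and from Actc1, Acta1 and Acta2, can map to either copy, and how such reads were counted is not given in the sources used here.

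**Figure D1:**
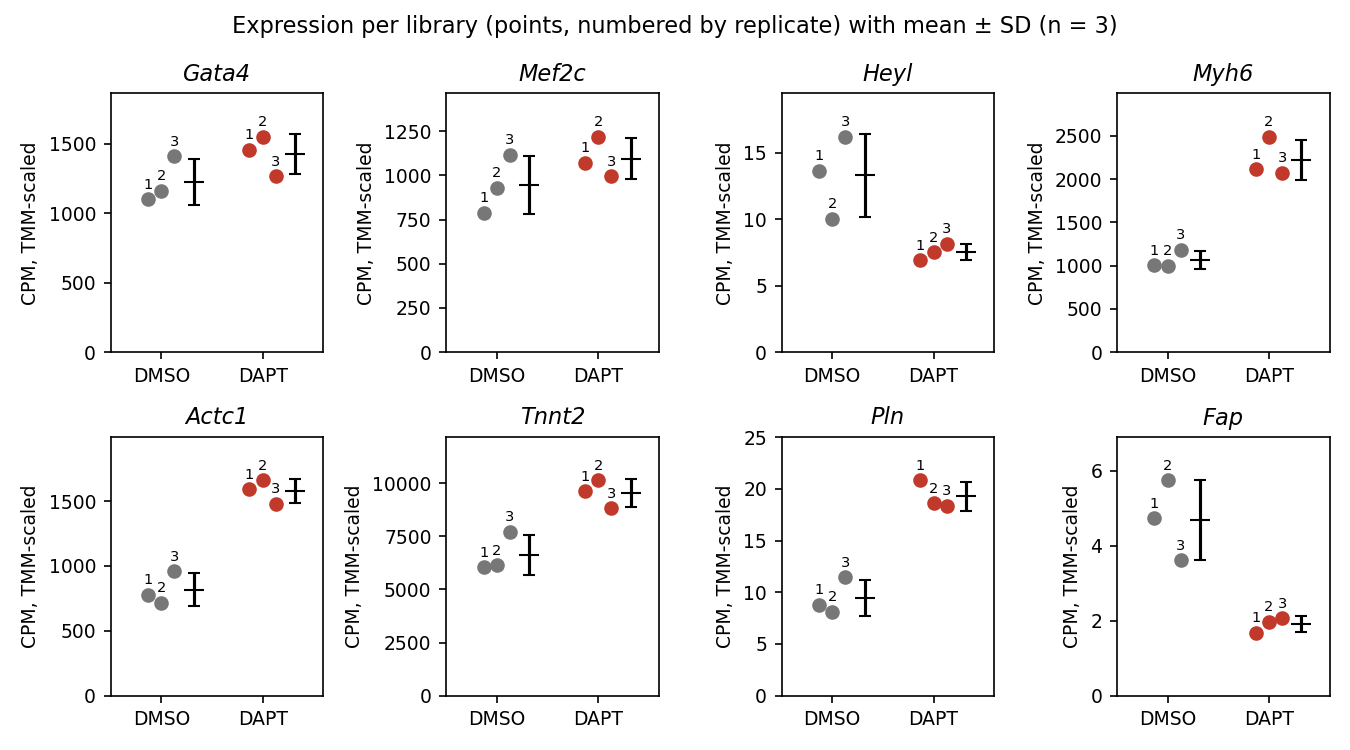
Expression of 8 named genes in each library, in CPM scaled by the trimmed mean of M-values (TMM), with points numbered by replicate and bars for the mean ± SD of 3 libraries per group. Myh6, Actc1, Tnnt2, Pln, Heyl and Fap show no overlap between DMSO and DAPT, whereas Gata4 and Mef2c overlap.

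Calcium handling genes were higher with DAPT, with 5 of 22 measured members rising across all genes, 17 not passing and 14 rising adjusted over the list alone. Pln, which encodes phospholamban, the inhibitor of the sarcoplasmic reticulum calcium pump (chromosome 10, 53337667 to 53345987), increased from 9.45 ± 1.75 to 19.3 ± 1.37 CPM (1.03 ± 0.13, edgeR adjusted p = 0.0212). Srl, for the sarcoplasmic reticulum protein sarcalumenin, increased from 60.3 ± 6.63 to 116 ± 16.3 CPM (0.94 ± 0.12, adjusted p = 0.0245). Sln, for the atrial pump regulator sarcolipin, increased from 63.6 ± 10.9 to 121 ± 7.95 CPM (0.93 ± 0.12, adjusted p = 0.0274). The median log2 fold change of the list was 0.39 (camera adjusted p = 1.69e-09; adjusted p = 0.35 with an estimated correlation). Without DMSO 3, 13 members rose and 1 fell, and without DMSO 2, DAPT 1, DAPT 2 or DAPT 3 none passed.

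Cardiac ion channel and conduction genes had a median log2 fold change of 0.29 over 22 measured members, of which 1 rose, 21 did not pass and 9 rose adjusted over the list alone. The gene that rose was Kcnj3, a subunit of the acetylcholine-activated potassium channel of atrial cells (chromosome 2, 55435970 to 55598145), which went from 0.868 ± 0.183 to 3.10 ± 0.009 CPM. Its log2 fold change of 1.84 ± 0.19 was the largest among the 96 genes that rose (edgeR adjusted p = 0.0184). The pacemaker channel gene Hcn4 was counted at 200 ± 18.1 and 314 ± 48.6 CPM and passed adjusted over the list alone (0.65 ± 0.12, adjusted p = 0.0067), not across all genes (adjusted p = 0.0616). The list was shifted by camera (adjusted p = 8.64e-05; adjusted p = 0.333 with an estimated correlation). Without DMSO 3, 7 members rose and 2 fell. Without DMSO 1, 2 rose, and without DMSO 2 or any 1 DAPT library none passed.

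Cardiac transcription factors other than those delivered were higher as a list (median log2 fold change 0.12 over 19 measured genes, camera adjusted p = 0.0072; adjusted p = 0.375 with an estimated correlation). None passed across all genes by edgeR, with 6 higher and 1 lower at an unadjusted p under 0.05 and 4 higher by DESeq2. Adjusted over the list alone 5 rose, among them the muscle methyltransferase gene Smyd1 (0.82 ± 0.15), Srf (0.29 ± 0.06) and Myocd (0.65 ± 0.16). Without DMSO 3, 4 rose and 2 fell. The groups overlapped in the mean log2 CPM of the list relative to all libraries. It was -0.171, 0.058 and -0.085 in DMSO 1, 2 and 3 and 0.017, 0.129 and 0.051 in DAPT 1, 2 and 3. The most abundant, Tead1, was counted at 612 ± 32.0 and 650 ± 82.0 CPM (edgeR adjusted p = 0.659). Nkx2-5, an early cardiac regulator, had 0 counts in each DMSO library and 0, 0 and 1 in the DAPT libraries, so no difference was detectable at this depth.

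Of 12 measured cardiac hormone and chamber genes, 2 rose (Myl7 and Sln), 10 did not pass, and 6 rose and 1 fell adjusted over the list alone (median log2 fold change 0.24, camera adjusted p = 0.0217; adjusted p = 0.333 with an estimated correlation). The atrial natriuretic peptide gene Nppa stood at 486 ± 77.8 and 616 ± 31.9 CPM (0.34 ± 0.11, edgeR adjusted p = 0.171; 0.00443 without DMSO 3). Among 20 measured target genes of Mef2 factors, 5 rose and 15 did not pass, and 10 rose and 1 fell adjusted over the list alone (median 0.39, camera adjusted p = 2.45e-08; adjusted p = 0.333 with an estimated correlation). Besides Myh6 they included Asb2, a ubiquitin ligase subunit of muscle, which increased from 36.7 ± 2.90 to 64.5 ± 4.80 CPM (0.81 ± 0.08, edgeR adjusted p = 0.0152). The M-band gene Myom1 increased from 98.6 ± 7.76 to 160 ± 17.8 CPM (0.70 ± 0.09, adjusted p = 0.0225). Klf2 went the other way and fell adjusted over the list alone (-1.26 ± 0.27, adjusted p = 0.0057). Without DMSO 3 the chamber list held 5 genes that rose and 2 that fell and the Mef2 list 10 and 1. Without DMSO 2 or any 1 DAPT library none passed in either list.

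Smooth muscle genes rose with DAPT too, 5 of 18 across all genes with 13 not passing, and 11 rose and 1 fell adjusted over the list alone. Myh11, the smooth muscle myosin heavy chain gene, increased from 461 ± 42.7 to 756 ± 59.7 CPM (0.71 ± 0.09, edgeR adjusted p = 0.0212). Mylk, for myosin light chain kinase, increased from 134 ± 13.8 to 218 ± 15.2 CPM (0.71 ± 0.09). Ramp1, a receptor activity-modifying protein gene, increased from 62.6 ± 9.79 to 116 ± 0.716 CPM (0.89 ± 0.10), both with edgeR adjusted p = 0.0212. The median log2 fold change was 0.31 (camera adjusted p = 4.74e-07; adjusted p = 0.333 with an estimated correlation). Of 34 skeletal muscle genes in the table, 11 reached the counts needed for a test. Of these, 2 rose, 9 did not pass, and 3 rose adjusted over the list alone (median 0.13, camera adjusted p = 0.0063; adjusted p = 0.333 with an estimated correlation). Acta1 increased from 73.2 ± 0.969 to 98.6 ± 5.16 CPM (0.43 ± 0.06, edgeR adjusted p = 0.0225). Myl1 increased from 14.1 ± 2.20 to 25.02 ± 2.65 CPM (0.83 ± 0.13, adjusted p = 0.0379). Acta1 is also expressed in embryonic heart. The skeletal myogenic regulators Myod1 and Myog had 0 to 2 counts in each library and were not tested. Without DMSO 3, 9 smooth muscle genes rose and 1 fell and 3 skeletal muscle genes rose. Without DMSO 2 or any 1 DAPT library none passed in either list.

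Fibroblast and extracellular matrix genes were lower with DAPT. Of 37 measured members 1 fell across all genes, 36 did not pass, and 23 fell adjusted over the list alone. The median log2 fold change was -0.58 (camera adjusted p = 4.43e-11; adjusted p = 0.35 with an estimated correlation). Fap, a surface protease of activated fibroblasts (chromosome 2, 62500943 to 62574075), fell from 4.70 ± 1.07 to 1.91 ± 0.205 CPM (-1.30 ± 0.20, edgeR adjusted p = 0.0373). Collagens passed only adjusted over the list alone, such as Col1a1 at 5583 ± 1365 and 3587 ± 335 CPM (-0.64 ± 0.18, edgeR adjusted p = 0.0403) and Col5a2 (-0.48 ± 0.11, adjusted p = 0.0233). Col3a1 did likewise at 2511 ± 1254 and 722 ± 135 CPM (-1.80 ± 0.48, adjusted p = 0.0449). The wide DMSO spread came with DMSO 3, whose mean log2 CPM over the list lay at -0.03 relative to the mean of all libraries. DMSO 1 and 2 lay at 0.59 and 0.34 and the DAPT libraries at -0.14 to -0.45. Without DMSO 3, 23 members fell across all genes, and without DMSO 2 or any 1 DAPT library none did. Cartilage and bone markers were also lower as a list (median -0.77, camera adjusted p = 0.00143; adjusted p = 0.333 with an estimated correlation). Of 13 measured, none passed by edgeR, 1 was higher and 7 lower at an unadjusted p under 0.05, DESeq2 called 2 lower, and 2 fell adjusted over the list alone. Their most abundant gene, Spp1, was counted at 1487, 561 and 521 CPM in DMSO 1, 2 and 3 and at 326 to 387 CPM with DAPT (edgeR adjusted p = 0.261; 0.0155 without DMSO 1). Without DMSO 3, 5 of these markers fell, and without DMSO 1, 3 did. TGF-β response genes were not shifted (21 measured, median -0.09, camera adjusted p = 0.256). None passed by edgeR, 2 were higher and 5 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher and 4 lower. Adjusted over the list alone Bmp2 rose and 4 genes fell, Inhba among them. Their most abundant member Thbs1 stood at 9171 ± 625 and 8547 ± 473 CPM (adjusted p = 0.571). Without DMSO 3, 2 of them rose and 6 fell.

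**Figure D2:**
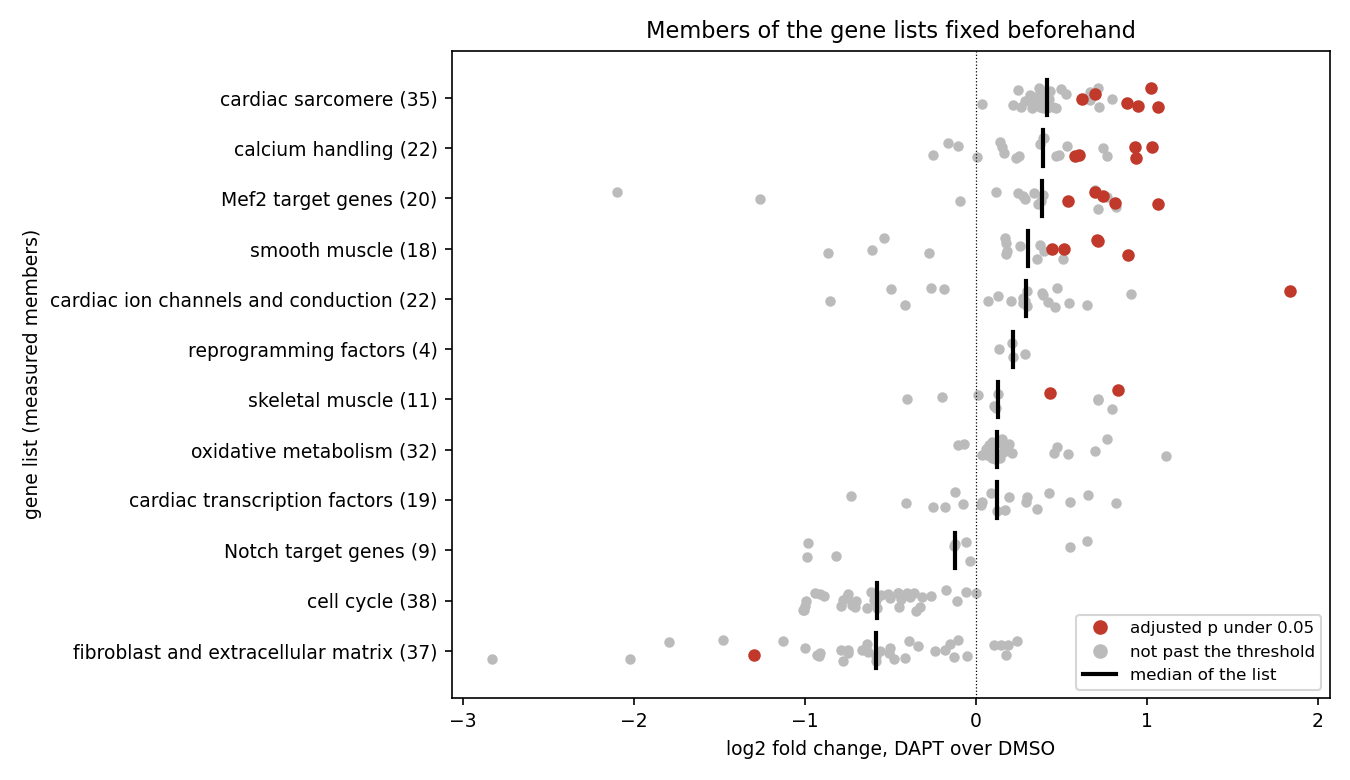
Log2 fold change, DAPT over DMSO, of each measured member of 12 gene lists, with the number of measured members in parentheses, red points for edgeR adjusted p under 0.05 and a bar at the median. The sarcomere points lie above 0 without exception, with a median of 0.41, and the fibroblast and cell cycle medians lie at -0.58.

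Cell cycle genes were lower with DAPT as a list, 37 of 38 measured members having a negative log2 fold change (median -0.58, camera adjusted p = 9.91e-17; adjusted p = 0.35 with an estimated correlation). None passed across all genes by edgeR, 31 were lower at an unadjusted p under 0.05, and DESeq2 called 18 lower. Adjusted over the list alone 31 fell. The mitotic kinase gene Plk1 went from 8.73 ± 1.27 to 4.33 ± 1.25 CPM (-1.01 ± 0.22). The replication licensing gene Mcm5 went from 14.4 ± 1.2 to 8.68 ± 1.73 CPM (-0.72 ± 0.15), and both had an edgeR adjusted p = 0.0193 over the list alone. Rrm2, the most abundant member, stood at 43.9 ± 3.52 and 43.9 ± 4.64 CPM (edgeR adjusted p = 0.993). Without DMSO 3, 17 members fell across all genes. Replication-dependent histone genes had a positive median (0.19 over 27 measured, camera adjusted p = 0.0235; adjusted p = 0.586 with an estimated correlation). None passed by edgeR, 4 were higher at an unadjusted p under 0.05 and 1 by DESeq2. The list was no longer shifted without DMSO 1 (adjusted p = 0.083), DMSO 2 (0.146) or DAPT 2 (0.0888), or without a filter on counts (0.119). Hist1h1c was counted at 210 ± 17.4 and 259 ± 10.6 CPM (edgeR adjusted p = 0.106; 0.00775 without DMSO 3). In mean log2 CPM of the histone list relative to all libraries, DMSO 3 (0.122) lay above DAPT 1 and 3 (0.023 and 0.002).

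Oxidative metabolism genes were slightly higher with DAPT, with 30 of 32 measured members positive and a median log2 fold change of 0.12 (camera adjusted p = 3.18e-07; adjusted p = 0.504 with an estimated correlation). None passed across all genes by edgeR, 7 were higher at an unadjusted p under 0.05, and DESeq2 called 4. The 4 that rose adjusted over the list alone were the muscle cytochrome oxidase genes Cox6a2 (1.11 ± 0.25) and Cox7a1 (0.54 ± 0.13), the mitochondrial biogenesis regulator Ppargc1a (0.70 ± 0.17) and Pdk4 (0.47 ± 0.12). Slc25a4, the most abundant member, stood at 830 ± 83.0 and 950 ± 28.7 CPM (edgeR adjusted p = 0.255). Without DMSO 3, 4 members rose, and without DMSO 1, 1. Mitochondrially encoded genes were higher as well (9 measured, 9 positive, median 0.22, camera adjusted p = 0.000116; adjusted p = 0.361 with an estimated correlation). None passed by edgeR, 5 were higher at an unadjusted p under 0.05 and 2 by DESeq2. Adjusted over the list alone mt-Nd6 and mt-Nd4 rose, and 3 genes passed without DMSO 3. The most abundant of the measured genes, mt-Co1, stood at 5196 ± 309 and 5813 ± 138 CPM (edgeR adjusted p = 0.310). Mitochondrial transcripts as counted took 1.69, 1.93 and 2.06% of the counts in DMSO 1, 2 and 3 and 2.16, 2.21 and 2.19% in DAPT 1, 2 and 3. In contrast to mt-Co1, mt-Co2, mt-Co3 and mt-Atp6 had 0 to 6 counts in each library and were not tested. The list and these percentages may therefore leave out part of the mitochondrial transcripts, and the cause was not tested. Ribosomal protein genes were lower as a list (20 measured, median -0.13, camera adjusted p = 4.91e-04; adjusted p = 0.571 with an estimated correlation). None passed by edgeR or DESeq2 and 3 were lower at an unadjusted p under 0.05. Rpl4 was counted at 702 ± 36.0 and 648 ± 29.5 CPM (edgeR adjusted p = 0.389), and these genes share reads with many pseudogenes. In mean log2 CPM of the ribosomal list relative to all libraries, DMSO 3 (-0.02) lay below DAPT 1 (0.021). Glycolysis genes were not shifted (16 measured, camera adjusted p = 0.317). Their median and camera's direction were positive and their mean negative (0.003 and -0.004). None passed by edgeR, 3 were higher at an unadjusted p under 0.05 and 3 by DESeq2, and Pfkm, Pfkp and Hk1 rose adjusted over the list alone. The list was higher without DMSO 1 (camera adjusted p = 0.0211), and in the 6 libraries it had an adjusted p = 0.586 with an estimated correlation. The glycolytic enzyme gene Pkm stood at 1108 ± 19.8 and 1169 ± 35.5 CPM (edgeR adjusted p = 0.533).

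Among 17 measured inflammatory cytokine and chemokine genes, 2 rose, 2 fell and 13 did not pass, and the list as a whole was not shifted (median -0.15, camera adjusted p = 0.792; 4 rose and 3 fell adjusted over the list alone). The monocyte chemoattractant genes Ccl7, from 96.6 ± 9.34 to 154 ± 5.33 CPM (0.67 ± 0.07, edgeR adjusted p = 0.0204), and Ccl2, from 113 ± 16.4 to 178 ± 8.65 CPM (0.65 ± 0.10, adjusted p = 0.0428), rose. The prostaglandin synthase gene Ptgs2 (-0.57 ± 0.09, adjusted p = 0.0373) and the alarmin gene Il33 (-1.16 ± 0.20, adjusted p = 0.0476) fell. Without DMSO 3, 2 rose and 4 fell, and without DMSO 2 or any 1 DAPT library none passed. Interferon response genes were not shifted (24 measured, camera adjusted p = 0.628). Their median and mean were negative (-0.14 and -0.26) against a positive camera direction, and 0 genes passed by edgeR, at an unadjusted p under 0.05 or by DESeq2. DMSO 1 held the highest value of 24 of the 24 genes, at a median of 2.91 times the mean of the other 5 libraries, and without it the list was higher with DAPT (camera adjusted p = 7.97e-15). In the 6 libraries the list had an adjusted p = 0.902 with an estimated correlation, the correlation between members being estimated at 0.91, and DAPT 2 lay level with DMSO 2 (-0.48 and -0.50 relative to the mean of all libraries). Bst2 from this list had a log2 fold change of -0.15 ± 0.47 (edgeR adjusted p = 0.890) with all libraries and 0.50 without DMSO 1 (adjusted p = 0.0462). Immediate early and stress genes were not shifted (20 measured, camera adjusted p = 0.803, median 0.02, mean -0.002, camera direction positive). None passed by edgeR, 1 was higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher. Hspb1 rose adjusted over the list alone, and Cdkn1a stood at 711 ± 50.5 and 777 ± 37.2 CPM (edgeR adjusted p = 0.384). Without DMSO 3, 1 of them rose and 3 fell.

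Of the marker lists of other cell types, 5 were not shifted in the 6 libraries. These were the endothelial (11 measured, median log2 fold change -0.02, camera adjusted p = 0.887), macrophage (5 measured, 0.00, adjusted p = 0.870), neural (11 measured, 0.06, adjusted p = 0.363), epithelial (9 measured, -0.05, adjusted p = 0.803, camera direction positive) and adipocyte lists (7 measured, -1.58, adjusted p = 0.240). Of their 43 genes none passed by edgeR, 2 were higher and 1 lower at an unadjusted p under 0.05, and DESeq2 called 1 higher. Flt1 was counted at 88.9 ± 19.8 and 112 ± 9.15 CPM (edgeR adjusted p = 0.305; 0.00669 without DMSO 3), Csf1r at 9.56 ± 1.19 and 10.7 ± 0.546 CPM (adjusted p = 0.45). Tubb3 stood at 149 ± 21.1 and 147 ± 10.7 CPM (adjusted p = 0.958) and Krt18 at 22.5 ± 2.85 and 25.8 ± 1.07 CPM (adjusted p = 0.305; 0.0448 without DMSO 3). The adipocyte values followed DMSO 2, which held the highest value of 7 of the 7 genes, with Lpl at 483 CPM against 112 to 170 CPM in the other libraries (edgeR adjusted p = 0.598). The list was lower with DAPT without DMSO 1 (camera adjusted p = 0.00115), with the replicate number as a block (0.0142) and without a filter on counts (0.00416). Without DMSO 2 the list was not shifted and camera's direction was positive (adjusted p = 0.743). In the 6 libraries it had an adjusted p = 0.806 with an estimated correlation. Of 9 measured mesothelial and epicardial markers, the uroplakin gene Upk3b fell from 14.2 ± 1.36 to 7.80 ± 1.16 CPM (-0.87 ± 0.13, edgeR adjusted p = 0.0342) and 8 did not pass (camera adjusted p = 0.792, median -0.11, 1 fell adjusted over the list alone). Without DMSO 3, 2 of these rose and 1 fell, and Upk3b did not pass without DMSO 2 (adjusted p = 0.122) or DAPT 1, 2 or 3 (0.116 to 0.181).

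**Figure D3:**
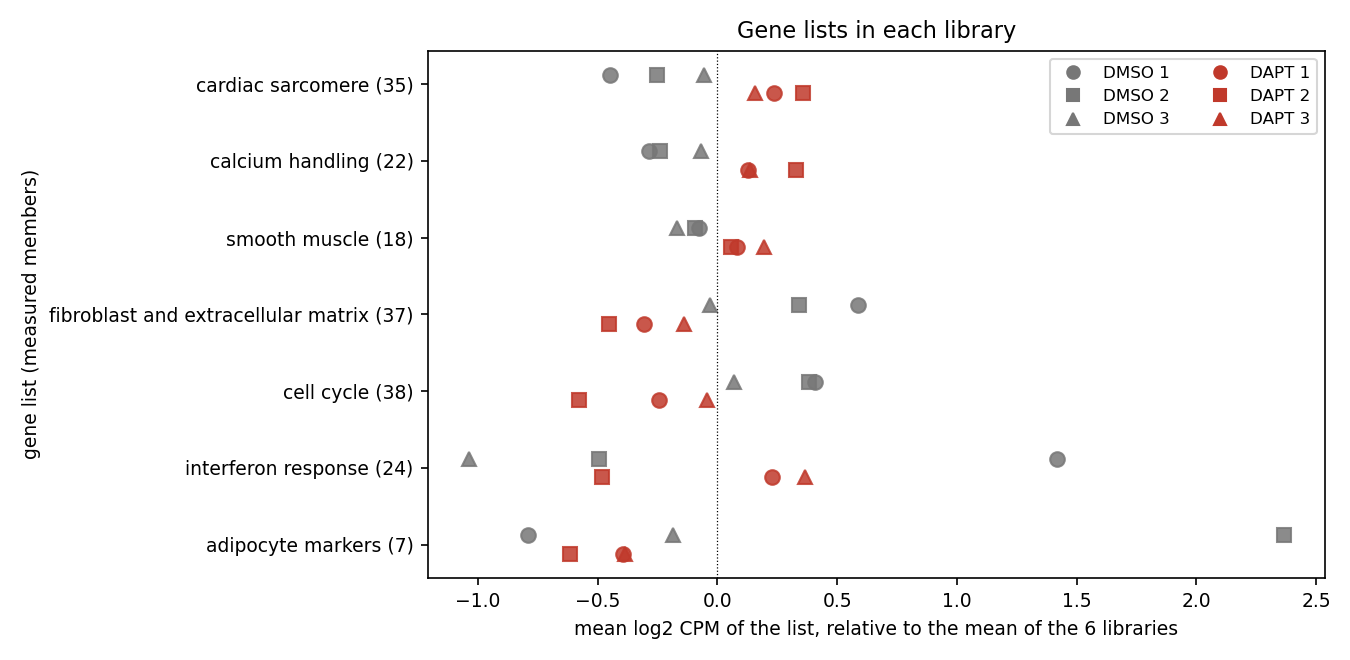
Mean log2 CPM of 7 gene lists in each library relative to the mean of the 6 libraries, with the number of measured members in parentheses, grey for DMSO, red for DAPT and a symbol for each replicate number. DMSO 3 lies at -0.03 in the fibroblast list and -0.06 in the sarcomere list, between the other DMSO libraries and the DAPT libraries, DMSO 1 stands apart in the interferon list at 1.42 and DMSO 2 in the adipocyte list at 2.37.

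Among called genes with a mean of at least 5 CPM and no overlap between the groups, the 5 largest rises were those of Hsd3b6, Gtsf1, Myh6, Ptprz1 and Pln. Hsd3b6, a steroid-converting dehydrogenase gene, increased from 4.57 ± 0.837 to 10.3 ± 1.99 CPM (1.17 ± 0.18, edgeR adjusted p = 0.042). Gtsf1, known for a role in germ cell transposon silencing, increased from 3.90 ± 0.86 to 8.74 ± 0.582 CPM (1.16 ± 0.16, adjusted p = 0.0274). Ptprz1, a receptor tyrosine phosphatase gene (chromosome 6, 22875502 to 23052916), increased from 38.8 ± 2.18 to 79.4 ± 5.16 CPM (1.03 ± 0.07) with the smallest adjusted p of all genes (0.00386), and was lost only without DAPT 3 (adjusted p = 0.0635). The largest fall among them was that of Npr3, the natriuretic peptide clearance receptor gene (chromosome 15, 11839896 to 11907287), from 25.4 ± 6.88 to 8.65 ± 1.07 CPM (-1.55 ± 0.20, edgeR adjusted p = 0.0328). It was followed by the secreted matrix-associated genes Srpx2 (-1.09 ± 0.17), Adamts12 (-0.89 ± 0.14) and C1qtnf3 (-0.88 ± 0.13) and by Upk3b. Without DMSO 2 or any 1 DAPT library, the adjusted p was 0.0688 to 0.24 for these falls and 0.0688 to 0.208 for the rises of Hsd3b6 and Gtsf1, and Srpx2 had 0.126 without DMSO 1.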

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

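The alternatives were planned, and the tests by splits of the libraries were given their bounds only after the counts were seen. DESeq2 size factors and total counts kept each count of called genes within 1.5 times and changed 0 of 29 list calls. Without a filter 357 genes were higher and 217 lower, with 96 and 22 of the 119 called genes among them. DESeq2 called 423 and 415, including all 119, limma-voom called 47 and 4, and an added log2 fold change of at least 1 left 10 and 6. Leaving out 1 library gave 0 to 827 genes higher and 0 to 1044 lower. The causes were not tested, except that fewer samples enter each left-out fit. Of the 52 named genes Bst2 alone changed sign with a call in either fit, at 0.50 without DMSO 1 (-0.41 to 0.50 over the libraries left out), while uncalled genes such as Lpl (0.18 without DMSO 2) also changed sign. Same-numbered libraries had correlations of deviations of 0.05, 0.06 and -0.20, and not every library correlated best with its own number. Deviations from a mean of 3 libraries depend on each other, so these values cannot decide whether the replicate numbers pair the samples. With the replicate block 1 gene was higher and 1 lower. With an estimated correlation the adjusted p was 0.571 for the factors, 0.504 for oxidative metabolism, 0.375 for cardiac transcription factors, 0.35 for calcium handling, extracellular matrix and cell cycle, and 0.333 for the sarcomere, ion channel, Mef2, skeletal and smooth muscle lists. By fry it was 0.341 for the factors, 0.164 for oxidative metabolism, 0.112 for transcription factors and extracellular matrix, 0.0961 for cell cycle and 0.0575 for the sarcomere and calcium lists, while it passed for smooth muscle and chamber genes (0.0134) and for ion channels, Mef2 targets and skeletal muscle (0.047). Leaving out 1 library moved the factor list between 0.00579 and 0.164, and the other 10 primary lists that passed kept their calls. For the 119 genes, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many, and the highest of the others gave 0. For the lists, 1 of 10 splits gave as many as the real 16, and the highest of the others gave 13. These splits are too few for a share under 0.05. Depth limits genes near 1 CPM, such as Hey1 and Kcnj3, and leaves Nkx2-5, Nrarp and Myl2 untestable.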

Other observations

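The genes in the first 2 paragraphs and the tests of DMSO 3 were chosen only after the results were seen. The tests with a covariate were chosen after the list shifts were seen but before their own values. Some called genes outside the fixed lists are given here as single genes, with no test of a group. The sarcolemmal gene Cav3 (0.70 ± 0.12, edgeR adjusted p = 0.0452), the myosin chaperone gene Unc45b (0.60 ± 0.08, adjusted p = 0.0274), the muscle splicing regulator Rbm24 (0.71 ± 0.09, adjusted p = 0.0212) and the cardiac muscarinic receptor gene Chrm2 (0.91 ± 0.15, adjusted p = 0.043) rose with DAPT, each with no overlap between 3 and 3 samples. Other genes picked from those called were the glycogen phosphorylase gene Pygm, which rose from 11.9 ± 2.21 to 22.7 ± 2.62 CPM (0.93 ± 0.14, edgeR adjusted p = 0.0379), Pygb (0.42 ± 0.07, adjusted p = 0.047), Gbe1 (0.39 ± 0.07, adjusted p = 0.0448) and Eno3 (0.62 ± 0.09, adjusted p = 0.0274). The glycolysis list was not shifted (camera adjusted p = 0.317, 0 of 16 genes passing). The chamber markers were unequal in level. The atrial light chain genes Myl7 and Myl4 stood at 407 ± 58.2 and 1627 ± 289 CPM in DMSO, while the ventricular light chain gene Myl2 had 1, 1 and 0 counts in DMSO and 4, 1 and 1 with DAPT, and Myl3 had 0 in every library, which allows up to 0.098 to 0.122 CPM.

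Of the called genes, 4 known from the NF-κB pathway or as its targets, all of which rose, are given here as single genes. The pathway was not tested and its called genes were not counted in full. In the inflammatory list 2 genes rose and 2 fell, Ptgs2 among the latter, and the list was not shifted (camera adjusted p = 0.792). Icam1 was counted at 15.8, 15.1 and 16.9 CPM in DMSO and 27.6, 29.1 and 25.1 CPM with DAPT (0.77 ± 0.08, edgeR adjusted p = 0.0184), Relb had a log2 fold change of 0.41 ± 0.06 (adjusted p = 0.0323), Tnip1 of 0.33 ± 0.06 (adjusted p = 0.0489) and Nfkb2 of 0.29 ± 0.05 (adjusted p = 0.0481). In the other direction, the mitotic genes Ncaph (-0.61 ± 0.10, adjusted p = 0.0447), Ercc6l (-0.95 ± 0.17, adjusted p = 0.0489) and Prr11 (-0.69 ± 0.12, adjusted p = 0.0489) and the collagen-processing genes Loxl3 (-0.69 ± 0.09, adjusted p = 0.0274) and Fkbp10 (-0.38 ± 0.06, adjusted p = 0.043) fell.

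DMSO 3 lay near the DAPT libraries on the first principal component, and leaving it out raised the calls to 827 higher and 1044 lower. The edgeR fit could not decide whether DMSO 3 was a DAPT library under a DMSO label, since 1 library gives no spread of its own. The log2 difference of DMSO 3 from the DAPT libraries was 1.11 for Heyl, -0.91 for Myh6 and -0.72 for Actc1. For the other tested always-named genes it was -0.31 to 0.38. Comparing each DAPT library in the same way, with DMSO 3 counted among the others, was no fair control. The standard error of Myh6 was 0.37 to 0.42 there, against 0.12 in the fit for DMSO 3. RNA from a DAPT culture mixed in at a fixed share was examined among genes with an absolute log2 ratio of at least 0.5. DMSO 3 lay 82.6% of the way from the other DMSO libraries to the DAPT mean for matrix genes (interquartile range 75 to 87.7). The position was 66.1% for cell cycle (46 to 71.1) and 45.8% for smooth muscle (20.8 to 73.7). It was 43.9% for sarcomere (27.2 to 58.8) and 32.1% for calcium handling genes (25.9 to 42.2). The smooth muscle, sarcomere and calcium positions rested on 10, 22 and 11 genes. Over all 18 measured smooth muscle genes DMSO 3 did not lie toward the DAPT libraries. Its mean log2 CPM relative to all libraries was -0.168, against -0.077 and -0.092 in DMSO 1 and 2 and 0.059 to 0.195 with DAPT. In 0 of 6 pairings of 1 other DMSO library with 1 DAPT library did a share lie inside the ranges of all 5 lists. These values cannot decide on mixing, since the unmixed culture of DMSO 3 was not measured and the other DMSO libraries differ from each other. Whether a true mixture would give 1 share inside all 5 ranges was not tested. Mixing stays open. A DMSO culture that had by itself lost more of the fibroblast programme also stays open, untested.

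The higher sarcomere list could come from more factor transcript or from fewer cells in a fibroblast state. The mean log2 CPM of the 4 factors was first taken as a covariate. The median log2 fold change of the 35 genes then went from 0.41 to 0.23 (interquartile range 0.17 to 0.46). The median of the extracellular matrix list went from -0.58 to -0.29. Myh6 still passed (0.91 ± 0.08, edgeR adjusted p = 0.0027). Transcript counts measure factor level with error, and such a fit can then leave a difference, so factor level as the whole cause stays open. With the level of the extracellular matrix list as a covariate the median fell to 0.06 (interquartile range -0.05 to 0.29), so a lower share of fibroblast-state cells stays open for most of the list. Myh6 then had 0.77 ± 0.12 against 1.07 ± 0.10 before, and its call ended (edgeR adjusted p = 0.118). The error grew and the estimate shrank. The adjusted p also depends on the p-values of the other genes, and 3 genes were called in all. The matrix level differs between the groups themselves, so an effect of DAPT on both lists stays open.

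In DMSO 2 the adipocyte marker Fabp4 was counted at 244 CPM against 3.15 to 10.6 CPM in the other 5 libraries, and 5 of the 7 measured adipocyte markers stood at least 2-fold above every other library. In DMSO 1, 7 of the 24 interferon genes stood at least 2-fold above every other library, with Isg15 at 151 CPM against 22.4 to 63.8 CPM, while 0 of the 5 macrophage markers were highest there.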
